A study of Mus musculus with 4 samples.

How the data were processed

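The data came from pancreas of mouse embryos at embryonic day 15.5. One genotype was wild type (WT) and the other, here called KO, lacked Mettl3, the catalytic subunit of the m6A methyltransferase, in Pdx1-positive pancreatic progenitor cells. Each genotype had 1 MeRIP library, made from RNA fragments pulled down with an m6A antibody, and 1 input library of the same kind of RNA without pull-down. Per the labels' protocols, total RNA was broken to about 200 nt before the pull-down, and libraries were sequenced on an Illumina instrument.

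The authors' processing reached these values as follows. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3 and aligned with HISAT2 2.0.4 to mm10. Per the file headers, each genotype has its own list of methylation sites, and the peak names in the files begin with MACS, a peak caller. The MACS version, the treatment of duplicate and multiply aligned reads and the step from all called peaks to the listed mRNA sites are not given in the sources used here. The deposited score of a site is the caller's p-value on a negative log10 scale multiplied by 10, per the file headers, and the lowest scores lie at 50, which is a p of 1e-05. The deposited fold enrichment is a ratio of MeRIP over input at the site as the authors' caller gave it, and that each MeRIP library was set against the input of its own genotype is assumed from the labels and was not checked. The deposited false discovery rate was read as percent, because its values reach exactly 100. No read counts were part of these lists, so sequencing depth is unknown, and no depth-based interval or detection limit can be given for a site.

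The score, fold enrichment and false discovery rate are the authors' values of single peaks. They were used here to describe, rank or filter sites within a list, and WT and KO values are set side by side without a ratio. Genotypes were compared by whether a site or gene was listed. With 1 library of each kind per genotype, no replicate error exists and no test between genotypes was run. The Wilson intervals (95%) cover counting error over sites or genes only, and sites and genes are not replicates.

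Coordinates were taken as 0-based starts, since 446 WT sites then begin exactly at an annotated gene start, against 36 under 1-based starts, and are printed 1-based on mm10. Gene names were updated through a table of GRCm38 genes, the same assembly, which has gene ends but no strand, exons or sequence. Of the WT sites, 10376 were named by gene identifier, 86 by transcript accession, 26 by an older symbol and 2 by symbol, and 24 kept the name in the file. For KO these numbers were 3873, 34, 12, 1 and 17. WT and KO sites were called shared when they overlapped by at least 1 bp, without regard to strand. A gene was called retained, or listed in both, when it had at least 1 WT site and at least 1 KO site, whether or not they overlapped.

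The gene lists, 21 in number, the rule for the genes to name and the first set of alternatives were fixed before the data were examined. The lists covered the m6A machinery, pancreatic progenitor regulators, endocrine progenitor and islet genes, acinar genes, duct and trunk epithelium, and the Notch, Wnt, Hippo, TGF-beta and BMP, and FGF and EGF receptor pathways. They also covered the cell cycle, apoptosis, chromatin regulators, housekeeping and ribosomal protein genes. The lists from outside the Pdx1 lineage were mesenchyme, endothelium, blood and immune cells, neural and glial cells, spleen, gut and liver, and mesenchymal transition and matrix regulators. For each list the retained share was set against 10000 random lists of the same size, drawn from genes with a WT site in the same of 10 equal bins of the gene's best WT fold enrichment. A list was said to stand apart below the 2.5th or above the 97.5th percentile, which describes these libraries and is no p-value. By chance 0.525 of 21 lists lie beyond each end. The 4 lineage lists and the 6 lists from outside the lineage were also pooled, leaving out 2 genes found in both.

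The rule for named genes took every listed member of the m6A machinery, Notch and endocrine lists and up to 4 members of each other list: the 2 with the highest WT fold enrichment among genes without a KO site, and the 2 with the highest KO fold enrichment. Over all genes it took the 8 highest of WT only, of KO only and of overlapping sites, skipping predicted genes and pseudogenes. Some genes that the rule took are not reported here. Members of the fixed lists named beyond this rule were chosen after their values were seen.

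The overlap code and the random lists were tested on simulated data. All 97 simulated overlaps matched a plain search. With 400 simulated lists of 20 genes per setting, built on the 5080 genes with a WT site, 2.25% of unchanged lists fell below the 2.5th percentile and 2.75% above the 97.5th. Of lists with retention lowered by 15 percentage points 27.2% were found, and of lists raised by 25 points 57.5%, so moderate shifts of a list of this size are often missed. In the simulation retention depended on the fold bin and not on WT sites per gene, and list members were drawn at random. It therefore cannot show how often unchanged lists whose genes carry many WT sites pass the percentiles. Alternatives changed the fold threshold, the merging of near sites, the overlap rule, the length of the WT list and the matching of random lists. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A limit on the false discovery rate, a joint matching on fold and WT sites, the overlap rule for pathways and the pooled outside lists without mesenchyme and matrix genes were added after seeing the data. The planned analyses of transcript region, of the DRACH motif and of random placement within transcripts were not run, since no exon annotation, strand or genome sequence was used here.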

Results

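The m6A sites listed for embryonic pancreas numbered 10514 in WT and 3937 in KO, so 2.67 times as many sites were listed in WT. They lay in 5080 genes in WT and 2776 genes in KO, a ratio of 1.83. A gene with sites carried 2.07 of them on average in WT and 1.42 in KO, and genes with a single site made up 54.2% of the WT genes and 73.1% of the KO genes. On each of the 20 chromosomes with at least 100 WT sites, WT exceeded KO by 2.36 to 3.26 times. The comparison asks which sites are no longer listed when the writer enzyme is deleted from the Pdx1 lineage, in a tissue that also holds cells outside that lineage. The lists hold no transcript levels, so a gene listed in WT only cannot be read as having lost its mark. Each genotype was represented by 1 MeRIP and 1 input library, so none of these differences can be set against a spread between replicates. The number of reads per library is unknown.

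The authors' values describe how strongly the sites stood out within each list. The median fold enrichment of MeRIP over input was 7.91 in the WT list (quartiles 6.49 and 9.54) and 6.20 in the KO list (quartiles 5.16 and 7.41). The false discovery rate was at most 20% for 9112 WT sites, 86.7% of the list, and for 0 KO sites. The lowest rate of any site was 9.75% in WT and 45.9% in KO. At most 50% was reached by 97.1% of WT sites and 70.1% of KO sites. In both lists rates of 100% were found among the sites with the highest scores. Every KO site named below therefore carries a false discovery rate of at least 45.9%. The pairing of each MeRIP library with the input of its genotype was assumed from the labels and not checked, which bears on every fold enrichment given.

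**Figure D1:**
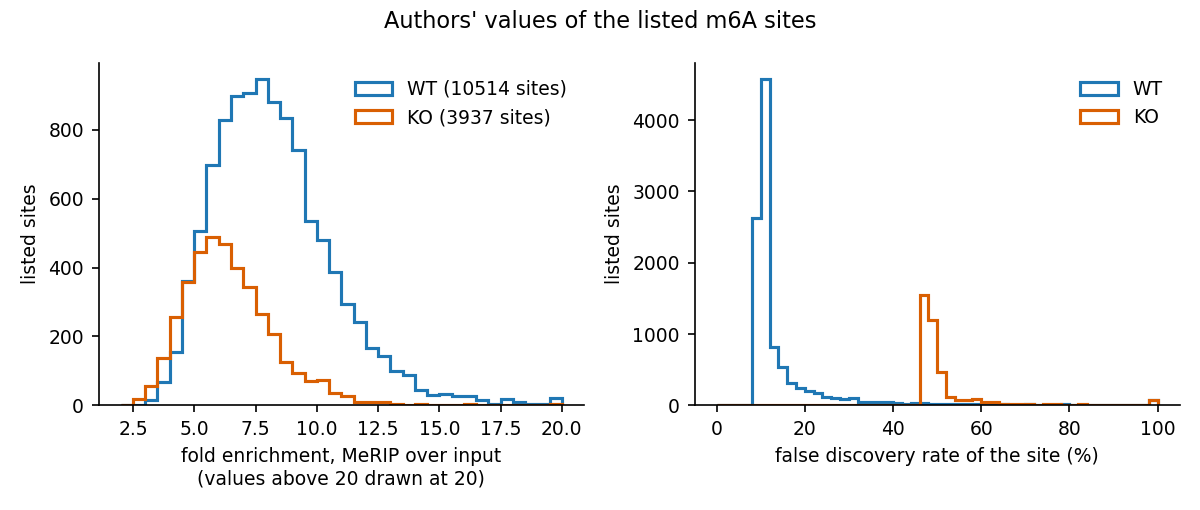
Left, numbers of listed sites by fold enrichment of MeRIP over input, and right, by false discovery rate in percent, for the 10514 WT and 3937 KO sites. WT rates start at 9.75% and KO rates at 45.9%.

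The ends of the listed intervals were largely the same in both genotypes where sites overlapped. Of 1289 overlapping pairs of a WT and a KO site, 1019 (79.1%) had the same start and end in both lists, and each genotype has its own numbered peaks. Among pairs under 300 bp, 782 of 815 (96.0%) were identical, and among longer pairs 237 of 474. Of the WT sites, 856 began or ended exactly at an annotated gene end, 8.14% (Wilson 95% interval 7.63 to 8.68), and of the KO sites 314, 7.98% (7.17 to 8.86). The median width was 203 bp in WT and 201 bp in KO. Whether these ends are those of peaks or of annotated blocks such as exons is not given in the sources used here. An overlap, or an identical site, is therefore taken to mean that the same listed interval held a peak in both genotypes and not that the peaks lay at the same position. The position of a peak within a long interval is not resolved, and exon, intron and UTR annotation was not used here.

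Most WT sites had no KO counterpart. A KO site overlapped 1287 of the 10514 WT sites, 12.2% (Wilson 95% interval 11.6 to 12.9), and 9227 WT sites had none. A WT site overlapped 1285 of the 3937 KO sites, 32.6% (31.2 to 34.1), so 2652 KO sites lay where WT had no listed site. Whether called but unlisted WT peaks lay there is unknown. At the level of genes, 1929 had sites in both lists, 3151 in WT only and 847 in KO only. The genes in both lists were 38.0% of the WT genes (36.6 to 39.3) and 69.5% of the KO genes (67.7 to 71.2). An overlapping pair of sites was present in 1043 genes, so a gene listed in both genotypes need not carry a site at the same place. When the WT list was shortened to the length of the KO list by fold enrichment, 12.8% of KO sites overlapped it and 1156 genes were shared. With sites of at most 50% false discovery rate only, 8.02% of WT sites were overlapped.

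Genes with many WT sites were more often listed in KO as well. Of the 2755 genes with 1 WT site, 26.2% had a KO site (24.6 to 27.9). This share was 40.2% for genes with 2 sites (37.3 to 43.2) and 79.2% for the 279 genes with 6 or more (74.1 to 83.6). Any KO site in the gene counted, overlapping or not, and gene length, exon number and transcript level were not accounted for. A WT site's own fold enrichment differed little between overlapped and other sites, with a median of 7.90 in the 1287 overlapped sites and 7.91 in the other 9227. The overlapped share among 10 equal groups by fold enrichment was 144 of 1052 sites in the lowest (Wilson 95% interval 11.7 to 15.9%) and 163 of 1051 in the highest (13.4 to 17.8%). In the groups between it ran from 10.3% to 12.9%, without a steady rise. By score it was 7.98% in the lowest group (6.50 to 9.78) and 18.9% in the highest (16.7 to 21.4).

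**Figure D2:**
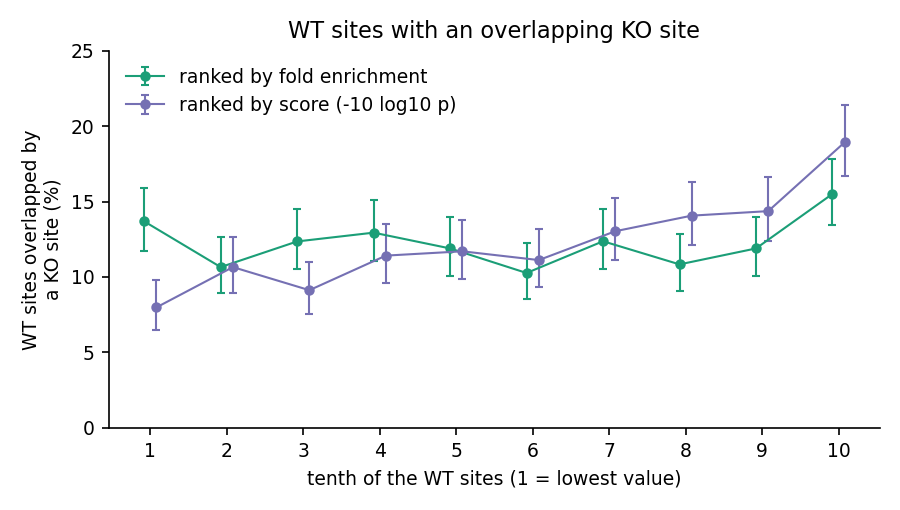
Percent of WT sites overlapped by a KO site, in 10 equal groups of the WT sites ranked by fold enrichment or by score, with Wilson 95% intervals. The share by score runs from 7.98% to 18.9%, while by fold enrichment it lies between 10.3% and that of the highest group, 163 of 1051 sites.

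The site with the highest fold enrichment among genes listed only in WT was in Ypel1 (chromosome 16, 17084527 to 17085623, 36.86-fold), although its false discovery rate was 100%. It was followed by Prpf18, a splicing factor gene (chromosome 2, 4635828 to 4635968, 20.92-fold, false discovery rate 30.6%). Ppie (20.43), Baiap2l1 (18.49), Mia3 (18.14), Atp9b (18.08), Kdm5a (17.95) and Ing3 (17.83) came next in best fold enrichment. Kdm5a, which encodes a histone H3 lysine demethylase, had 6 WT sites, the strongest with a false discovery rate of 92.2%, and Mia3 had 5. Among genes listed only in KO, E2f7, a cell cycle repressor, had the highest fold enrichment (19.09, chromosome 10, 110782198 to 110782619, false discovery rate 100%). Fzr1 (16.31), AK144545 (14.42), Gabpb1 (13.22), Zbed5 (12.73), Pak4 (12.24), Phka1 (12.24) and Pnp2 (11.75) followed. Among genes with overlapping sites in both lists, the best KO fold enrichment was 25.62 in Plac9a, 21.78 in Dact1, 17.33 in Amy1, 17.22 in Pum3, 16.15 in Ttc27, 16.06 in Aco1, 14.86 in Rbm6 and 14.66 in Camk1d. In Dact1 and Pum3 that value belongs to a KO site without a WT partner. The false discovery rate of these 8 sites was 100%, except for 92.8% in Rbm6. Plac9a, Pnp2 and Amy1 have close gene copies that can share reads, so their sites are uncertain.

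Mettl3 itself had no listed site in either genotype, and a site list holds no transcript level, so the deletion cannot be checked from these lists. Of the 21 members of the m6A machinery list, 17 had a WT site, and 9 of these also had a KO site. Both-listed members were the writer-complex genes Mettl14, Wtap, Virma, Zc3h13 and Cbll1, together with Mettl16, Ythdf3, Igf2bp1 and Igf2bp3. Virma had 6 WT sites with a best fold enrichment of 12.41 and 2 KO sites with a best of 8.44. The demethylase genes Fto (2 sites, best 8.83) and Alkbh5 (1 site, 8.88) were listed in WT only. So were the reader genes Ythdf1, Ythdf2, Ythdc1 and Igf2bp2, and Rbm15 and Hnrnpc. The share listed in both, 52.9%, lay at percentile 93.2 of matched random lists. Of the 9, only Wtap, Virma, Cbll1 and Ythdf3 had an overlapping pair of sites, and with such a pair needed the list lay at percentile 71.5.

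Genes assigned in advance to the Pdx1 lineage were examined because the deletion was made there. That assignment, like that of the lists from outside the lineage, was not checked against expression in this tissue. Among pancreatic progenitor regulators 11 had a WT site, and 3 of them, Nkx6-1, Hnf4a and Nr5a2, also had a KO site (percentile 27.9 of matched random lists, and 2.33 with the WT list shortened to the KO length). Sox9, needed for progenitor maintenance, had 1 WT site (6.77) and no KO site. Gata6, Prox1, Mnx1, Onecut1 and Tcf7l2 were also listed in WT only. The Nkx6-1 site on chromosome 5, 101661834 to 101662006, was identical in both lists, with a fold enrichment of 5.96 in WT and 6.02 in KO. No site was listed for Pdx1 or Ptf1a in either genotype. At the level of sites, 1 of the 23 WT sites of this list was overlapped in KO, 4.35% (Wilson 95% interval 0.772 to 21.0).

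Of the endocrine progenitor and islet genes, 16 had a WT site and 5 of these also had a KO site (percentile 40.2). The 5 were Nkx6-1, the granin genes Chgb and Scg3, the glucagon gene Gcg and the hormone-processing gene Cpe. Scg3 had 8 WT sites and 1 KO site, and Cpe had 4 and 1. The Cpe sites did not overlap, while each of the other 4 genes had an overlapping pair. The 11 genes listed in WT only included the glucose transporter gene Slc2a2 (10.70), Sst (9.17), Myt1 (8.32) and Ins2 (6.71), given with their best fold enrichment. Slc30a8, Glis3, Chga, Rfx3, Tox3 and St18 were also listed in WT only. Pcsk1 (8.26) and Pcsk2 (6.14), which encode prohormone convertases, were listed in KO only. No site was listed for Neurog3 in either genotype. Of 8 acinar genes with a WT site 3 also had a KO site, Nr5a2, without overlap, and the amylase genes Amy1 and Amy2a5 (percentile 52.8). The trypsin gene Prss1 (best 11.37), Cuzd1 (9.74), Spink1 (9.64), Gp2 (7.08) and Reg1 (6.42) were listed in WT only, and Cpb1 and Cela1 in KO only. Of 14 duct and trunk epithelium genes 5 had sites in both lists (percentile 49.1), namely Prom1 (6 WT and 2 KO sites), Bicc1 (11 and 4), Anxa2 (3 and 1), Krt7 and Cdh1, of which Anxa2 and Cdh1 had no overlapping pair, while Dcdc2a (2 WT sites, best 9.64) had none. None of these 4 lists stood apart from random lists matched on fold enrichment over the full lists.

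In the Notch pathway 15 genes had a WT site and 5 of them a KO site (percentile 42.3). The ligand genes Dll4 and Jag1 were listed in WT only. Dll4 had 2 sites, the stronger on chromosome 2 at 119332143 to 119332845 with a fold enrichment of 17.76, and Jag1 had 1 with 10.65. The receptor gene Notch1, Rbpj, which encodes the DNA-binding partner of the Notch intracellular domain, Mib1, Numb, Psen2, Maml3 and Nrarp were also listed in WT only. Notch2, Heyl, Maml1 and the sheddase genes Adam10 and Adam17 were listed in both. Adam10 had 8 WT sites and 2 KO sites. All of these 5 but Notch2 had an overlapping pair. Spen was listed in KO only, and Hes1 in neither. In the Wnt pathway 15 of 18 genes with a WT site had no KO site, among them Lgr4 (best 11.25) and Tcf7l2 (6 sites, best 10.95), and the share listed in both of 16.7% lay at percentile 4.23, within the bounds. It lay at 1.00 with sites of at most 50% false discovery rate only, at 2.53 when matched on WT sites, at 18.3 with the upper 75% of each list, at 10.6 with a fold enrichment of at least 5 and at 43.8 with an overlapping pair needed. The larger KEGG set for Wnt signalling, examined after seeing the data, had 23 of 55 genes listed in both (percentile 59.0). Lrp5, Dvl3 and Tcf7l1 were listed in both, and Fzd6, Dvl1 and Rnf43 were listed in KO only. In the Hippo pathway 9 of 12 genes were listed in WT only, including the kinase genes Lats1 (15.08) and Lats2 (12.75), and Wwtr1, Taok1 and Fat1 were listed in both (percentile 11.5). TGF-beta and BMP genes were listed in both in 7 of 15 cases (percentile 79.2), among them Smad1 and Smad5, whereas Bmpr2 had 6 WT sites and none in KO. FGF and EGF receptor pathway genes were listed in both in 7 of 13 (percentile 92.7, and 98.0 with a fold enrichment of at least 5), with Fgfr2 and Braf in both lists. An overlapping pair was present in 3 of these 7 genes and in 4 of the 7 of the TGF-beta and BMP pathway. Further KEGG sets were examined after seeing the data. Listed in both were 10 of 23 Notch genes (percentile 59.3), 19 of 61 Hippo genes (3.75), 12 of 24 TGF-beta genes (84.8) and 14 of 38 ErbB genes (26.7). With an overlapping pair needed these sets lay at 90.3, 36.3, 98.9 and 2.055 in that order. None of the 5 fixed pathway lists passed the percentiles set with the full lists and matching on fold enrichment.

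The list that stood apart was that of mesenchyme genes, which were assigned to cells outside the deleted lineage. Of its 20 genes with a WT site, 12 also had a KO site, 60.0% against a median of 35.0% in matched random lists (percentile 98.1). The genes listed in both included Fn1, which encodes fibronectin (9 WT and 6 KO sites, 4 of them shared), Fbn2, a fibrillin gene (5 and 9), Fbn1 (6 and 8), Col6a3 (7 and 4) and Pdgfra (5 and 2). Vim (2 WT sites, best 11.12) and Cdh11 (3 WT sites, best 12.16) were listed in WT only. When random lists were matched on the number of WT sites per gene instead, the list lay at percentile 83.6, and with a fold enrichment of at least 5 at percentile 70.7. With an overlapping pair needed and matching on fold enrichment, 11 of the 20 genes counted and the list lay at percentile 99.98. The overlapping pair rule was not run with matching on WT sites per gene, so the number of sites is not accounted for there. At the level of sites, 17 of its 68 WT sites were overlapped in KO (Wilson 95% interval 16.2 to 36.4%), against 12.2% of all WT sites.

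The other lists from outside the lineage held few listed genes. Endothelial genes were listed in both in 2 of 5 cases (percentile 51.3), with Nrp1 and Cdh5 in both lists and Dll4, Nrp2 and Ets1 in WT only. Blood and immune genes were listed in both in 2 of 5, Alas2 and Cd34 (percentile 58.7), where Tfrc and Slc4a1 were listed in WT only and Runx1 and Csf1r in KO only. Neural and glial genes were listed in both in 1 of 3 (percentile 61.9), the receptor gene Ret, while Ednrb was listed in KO only. Of the spleen, gut and liver genes 1 of 5 was listed in both (percentile 18.3), Ttr, and the liver genes Alb (best 13.87) and Afp (13.04) were listed in WT only. Mesenchymal transition and matrix regulators were listed in both in 8 of 15 cases (percentile 88.0), with Col4a2 and Nid1 in both lists and Zeb2 (4 WT sites, best 14.38) in WT only. Pooled, 13 of 42 lineage genes were listed in both, 31.0% (Wilson 95% interval 19.1 to 46.0, percentile 23.5). Of the genes from outside the lineage 25 of 50 were (36.6 to 63.4%, percentile 97.4). The difference of -19.0 percentage points lay at percentile 2.98 of matched random pairs of lists, of which the central 95% lay between -19.8 and 18.9 points, and at percentile 8.54 when matched on WT sites per gene.

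Among general gene groups, chromatin regulators were listed most often. Of these, 30 had a WT site and 17 a KO site as well (percentile 97.0, 62.2 when matched on WT sites per gene and 98.2 without matching). An overlapping pair was present in 9 of the 17 (84.3 with such a pair needed). Setd2, which encodes a histone H3 lysine methyltransferase, had 8 WT sites (best 16.56) and no KO site, Hdac1 had 2 (best 14.90) and none, Arid2 was in both lists and Ezh1 in KO only. Cell cycle genes were listed in both in 5 of 15 cases (percentile 31.7), Mcm6 among them, while Ccnb2 and Mcm3 were listed in WT only and Cdkn2c in KO only. Although these 5 genes had sites in both lists, 0 of the 32 WT sites of the list were overlapped in KO, and with an overlapping pair needed for a shared gene the list lay at percentile 1.18. The larger KEGG cell cycle set, examined after seeing the data, had such a pair in 13 of 45 genes and lay at percentile 73.7, so the low value did not extend to it. Apoptosis genes were listed in both in 3 of 12 cases (percentile 15.1), with Apaf1 and Birc6 in both lists and Bbc3 (15.51) and Xiap (13.20) in WT only. Of the housekeeping genes 1 of 10 was listed in both (percentile 6.01), and Pgk1 and B2m were listed in WT only. Ribosomal protein genes were listed in both in 1 of 6 cases (percentile 21.8), Rpl8, while Rps24 and Rpl3 were listed in WT only and Rpl27 in KO only. With any KO site counted and matching on fold enrichment, none of these 5 lists passed the percentiles set.

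**Figure D3:**
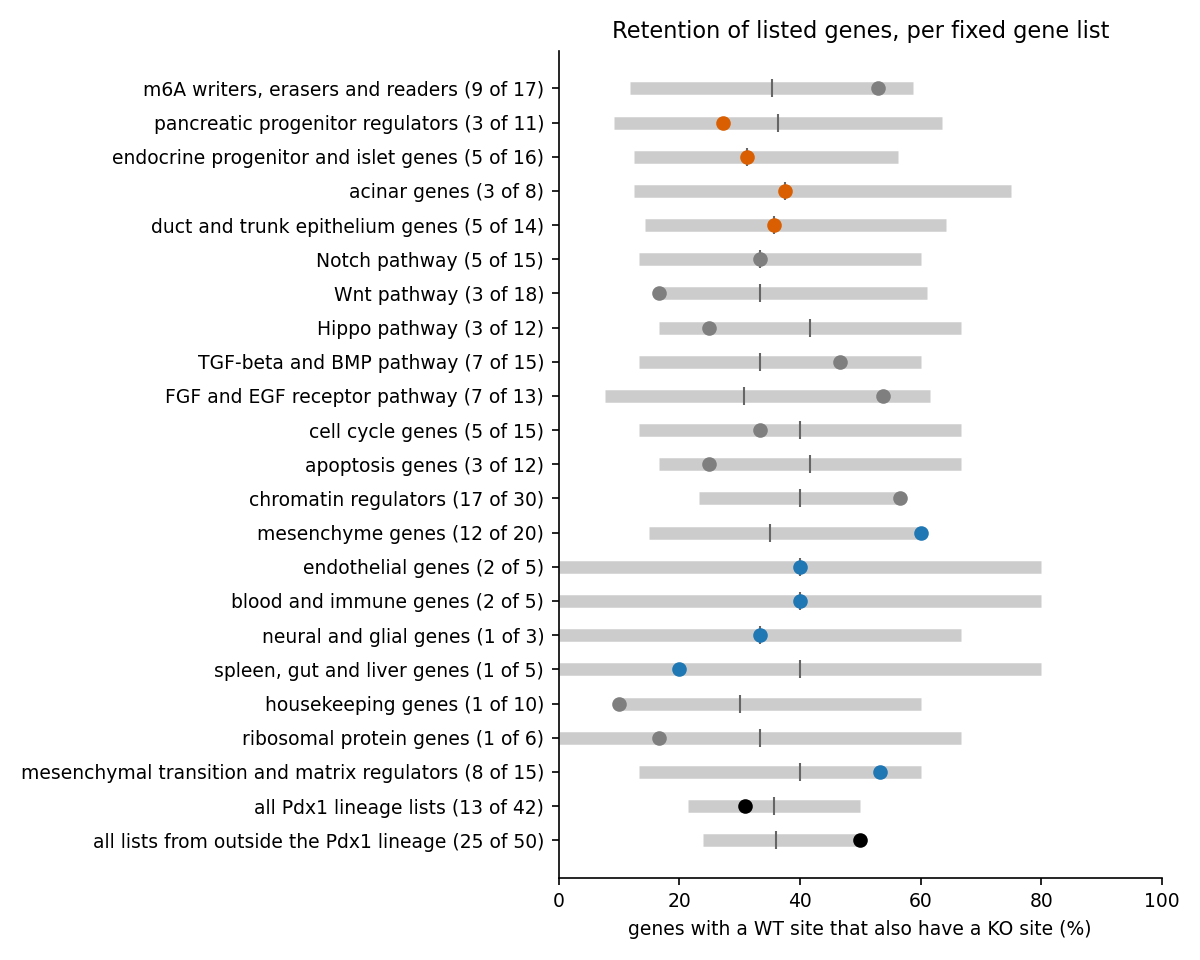
Percent of genes with a WT site that also have a KO site, per gene list, as a dot with the numbers beside the name. Grey bars span the central 95% of 10000 random lists matched on fold enrichment, ticks mark their median, orange dots are Pdx1-lineage lists, blue dots lists from outside the lineage, grey dots other lists and black dots the pooled lists. The mesenchyme list, at 60.0%, lies at percentile 98.1.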

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

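The test of unlisted peak density and the test of score within groups of like fold enrichment were written down before their results were seen, but the demand that the first cover at least 50% of the genes in each list was added afterwards. The tests of the highest peak numbers, of lineage genes, with and without the mesenchyme and matrix lists, and of gene copies were chosen only after the results were seen.

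The listed sites are a small part of what the caller numbered, and that part differed between genotypes. Peak numbers rise along each chromosome without exception in both lists, and the highest number is 94812 in WT and 99502 in KO. At least 95565 numbered KO peaks and 84298 numbered WT peaks are therefore absent from the lists, which hold 11.1% of the WT numbers and 3.96% of the KO numbers. Fewer called peaks overall in KO are argued against as the cause of the short KO list, since the highest KO number was 1.05 times that of WT whereas KO had 0.374 times as many listed sites. That reading takes the highest number to stand for all called peaks, and the order of numbers across chromosomes was not checked. An excess of KO peaks in unlisted parts of genes stays open. Between the first and last listed site of a gene there were 16.0 unlisted peaks per 100 kb in WT and 16.8 in KO, a ratio of 1.05 (95% bootstrap interval over genes 0.955 to 1.14), and 0.972 (0.873 to 1.06) in the 524 genes with at least 2 sites in both lists. The value near 1 met what had been written down as speaking against such an excess. However, the density can be measured only in genes with at least 2 sites in a list, which were 45.8% of the WT genes and 26.9% of the KO genes. Genes without KO sites are left out by this rule, so for them the test decides nothing. Loss of Mettl3 in the Pdx1 lineage stays open as a hypothesis, because the gap in retention between lineage and other genes lay at percentile 2.98 of random pairs, just inside the bound set, and at 8.54 when matched on WT sites and 7.99 when matched on both. Without the mesenchyme and matrix lists, 6 of 18 genes from outside the lineage were listed in both, 33.3% (Wilson 95% interval 16.3 to 56.3), against 31.0% of lineage genes. Among the fixed lists of neither kind, the share ran from 1 of 10 housekeeping genes to 17 of 30 chromatin regulators. A low share was therefore not particular to lineage genes. An unknown rule by which numbered peaks were reduced to listed sites also stays open and was not tested.

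In both lists the false discovery rate rose at the highest scores, to 99% or more in 68 WT sites and 77 KO sites. Reads shared between gene copies may contribute. Of the 68 WT sites 25% lay in pseudogenes, predicted genes or genes with a named near copy (Wilson 95% interval 16.2 to 36.4), against 9.08% of the other WT sites (8.54 to 9.64). In KO these shares were 26.0% (17.5 to 36.7) and 8.68% (7.83 to 9.61). Such genes were enriched, but most of these sites lay elsewhere, so this explanation can neither be accepted nor excluded for the whole pattern. No biological explanation was tested.

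Retention of WT sites did not rise steadily with their fold enrichment, although it was highest in the top group. It rose with their score, which grows with read number as well as with fold. Read coverage at the site is a candidate explanation. Among WT sites in 3 equal groups by fold enrichment, sites with the highest scores were overlapped in KO 1.95, 1.63 and 1.47 times as often as sites with the lowest scores. Each group still spans a range of fold enrichment. In the group of highest fold enrichment the shares were 16.4% (14.3 to 18.6) and 11.1% (9.45 to 13.1). On this reading, whether a WT site recurs in KO would depend in part on transcript abundance, which these lists do not give. No biological explanation was tested.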

How the results depend on the processing

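Numbers of WT and KO sites stayed within 1.5 times of those reported with a fold enrichment of at least 5, merged sites and the false discovery rate limit. The limits of false discovery rate and the joint matching on fold and WT sites were chosen after seeing the data. The false discovery rate limit also removes sites with the highest scores, so values under it do not describe the strongest sites. The 12.2% of WT sites overlapped in KO became 9.26% with the upper 75% of each list by fold enrichment, 9.12% with a fold enrichment of at least 5, 11.2% with centres within 100 bp and 8.02% with a false discovery rate of at most 50%. The 32.6% of KO sites overlapped in WT became 24.7%, 29.1%, 30.0% and 29.6% in that order, and 12.8% with the WT list shortened to the KO length. Shared genes, 1929, became 1156 with the shortened list and 1043 when an overlapping pair was needed. As a share of WT genes, 38.0% became 32.6% (upper 75%), 32.0% (fold of at least 5), 43.9% (shortened list), 20.5% (overlapping pair) and 30.3% (false discovery rate). The pooled genes from outside the Pdx1 lineage, at percentile 97.4 and within the bound, moved to 98.0 with the false discovery rate limit. With overlapping pairs and matching on fold they moved to 99.9. They fell to 76.9 when matched on WT sites, 80.0 when matched on both and 83.85 with the upper 75%. With a fold of at least 5 they lay at 90.2, with the shortened list at 95.1 and without matching at 96.0. The pooled lineage genes stayed between percentiles 11.7 and 64.6 in the alternatives run. Of 166 combinations of a single list and an alternative, leaving out merged sites, 155 kept their side of the percentiles, 11 did not and 0 turned from one end to the other. Only the mesenchyme list lay beyond a bound as reported, so only it could turn. The 155 are mostly lists that stayed within the bounds. Of those 11, 6 were the mesenchyme list, and 1 each the progenitor, Wnt, FGF and EGF, cell cycle and chromatin lists. Among these combinations the mesenchyme list stayed above the bound only with an overlapping pair needed (99.98) and without matching (97.6). The call of 12 of 140 named genes changed with a fold of at least 5, of 21 with the upper 75%, of 26 with the false discovery rate limit and of 48 with the shortened list. The causes were not tested. A p of at most 1e-05 removed no site, no interval was listed more than once, other overlap rules cannot change gene retention, and the upper 75% fixes the number of sites, so those alternatives were void. Merging near sites left the 1929 shared genes and the list percentiles unchanged. The alternatives of transcript region and motif were not run. No paired analysis was possible because each group held 1 library. Depth is unknown, and the list sizes of 3 to 30 genes limit what the percentiles can show.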

Other observations

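KEGG pathways named in the files were also examined, including genes of the fixed lists, and every test in this part was chosen after seeing the data. Of 149 pathways with at least 20 genes that had a WT site, 7 lay above the upper bound set for random lists matched on fold enrichment and 2 below the lower, where chance gives 3.73 at each end. Of the 7, 3 also passed when matched on the number of WT sites per gene. In fatty acid metabolism 15 of 21 genes with a WT site also had a KO site (percentiles 99.8 and 99.9). Cpt1a, which encodes the rate-limiting enzyme of mitochondrial fatty acid import, Acsl1, Acsl3, Acsl4 and Acadm had sites in both lists that did not overlap, and Acadl and Hadh had overlapping sites. Protein processing in the endoplasmic reticulum, with 41 of 76 genes (percentiles 99.2 and 97.7), and the adipocytokine pathway, with 16 of 26 (97.9 and 99.7), were the others. The adipocytokine pathway shares Acsl1, Acsl3, Acsl4, Acsl5 and Cpt1a, all listed in both genotypes, with fatty acid metabolism. Its result is therefore not independent of that pathway. When an overlapping pair of sites was needed, none of these 3 pathways stood apart. Fatty acid metabolism then had 6 of 21 genes (percentile 73.3), protein processing 18 of 76 (63.5) and the adipocytokine pathway 3 of 26 (7.62). Under this rule 6 pathways lay above the upper bound and 5 below the lower. Above it under both rules with matching on fold enrichment were regulation of the actin cytoskeleton, with 43 of 80 genes listed in both (percentile 99.3) and 27 with an overlapping pair (99.4), and the Salmonella infection pathway, with 18 of 30 (98.9) and 12 (98.8). With any KO site counted and matching on WT sites they lay at 95.7 and 96.9, within the bound. For pathways the overlapping pair rule was run with matching on fold enrichment only.

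At the lower end, NOD-like receptor signalling had 4 of 21 genes listed in both (percentile 1.33, and 7.14 when matched on WT sites) and 0 of 21 with an overlapping pair (0.16), with Tab2, Casp8, Chuk and Mapk9 listed in WT only. The ribosome pathway, which shares Rps24, Rpl3 and Rpl8 with the fixed ribosomal list, had 9 of 41 (2.31, and 4.92 when matched on WT sites). With an overlapping pair it had 8 of 41 and lay at percentile 55.4. The set of all metabolic pathways, with 121 of 346 genes, lay at percentile 4.19 (24.4 when matched on WT sites), and pyrimidine metabolism, with 7 of 32, at 2.52 (5.3 when matched on WT sites). The spliceosome, with 22 of 68 genes, lay at 7.60 and was the 1 pathway below the lower bound when matched on WT sites (1.965). With an overlapping pair needed and matching on fold enrichment it lay at 26.0. Pancreatic secretion lay at percentile 50.5 and insulin secretion at 51.9. The genes named here were chosen after their values were seen.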
